A study of Homo sapiens with 6 samples.

How the data were processed

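RNA-seq was carried out on DB cells, an established human line of diffuse large B-cell lymphoma, in 2 groups named in the labels as DB_ZHX2 and DB_ZHX2_Mut4, with 3 libraries labelled in each. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads, and libraries were made with a dUTP-labelled second strand. The submitters' processing notes name fastp, HISAT2, StringTie and edgeR and the genome build GRCh38, with no versions, and how each was set is not given in the sources used here.

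A single table of 29571 genes was deposited, holding for each library the FPKM, a length- and depth-normalized level per gene, per the file headers. The same deposited table gives for each gene a linear ratio, its log2 value, a p-value and a q-value, per the file headers. The deposited ratio was checked against the FPKM columns: it is the level of DB_ZHX2 replicate 1 over that of DB_ZHX2_Mut4 replicate 1, so the deposited log2 fold change has the opposite sign to the ratios printed below. The authors' p-values and ratios were used only to describe their table. The column marking the direction of regulation was not used. In the upper part of the table (201 of the rows up to row 5989), the letters "up" inside words had been replaced by "down". The 15 gene symbols altered in this way were restored by gene ID from a table of human gene names, and all 15 matched.

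The table holds no counts, so total depth is not known. FPKM multiplied by transcript length, over genes with 1 annotated transcript in GENCODE v29, piled up at common steps in the low values. In replicate 1 the larger step was 0.0640 FPKM kb in DB_ZHX2_Mut4 and 0.0654 in DB_ZHX2. Set against that of DB_ZHX2_Mut4 replicate 1, the step was 1.02, 1.36 and 0.917 times as large in DB_ZHX2 replicates 1, 2 and 3. Since it moved with the constants described next, and which column is unscaled is not known, no relative depth, counts or counting intervals were derived.

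Before any test, the columns of a group were compared. Within each group the 3 columns were constant multiples of one another, gene by gene, within a relative tolerance of 1e-06, except at ATG5 and ACSL1 in DB_ZHX2, and the low-value steps scaled by the same constants. They were therefore counted as 1 sample per group, and the mean of the 3 columns was used as its level. The design fixed before the data were examined had called for a limma fit on 3 against 3 libraries, with camera and fry tests of gene lists. Neither was run, since no residual degrees of freedom remained between independent samples, and no p-value, standard error or standard deviation between replicates is given.

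Levels were compared as log2(FPKM + 1) of DB_ZHX2_Mut4 minus that of DB_ZHX2, which understates the ratio of low genes. All folds below are on this scale unless said otherwise. Genes needed at least 1 FPKM in at least 3 of the 6 columns (12646 genes, 42.8% of the table). In 3 rows (ATG5, ACSL1 and SLC7A11), the FPKM, the deposited ratio and the deposited log2 value did not match one another, and these were left out of counts and lists, leaving 12643 genes. Counts were made at 2-fold for genes and at 1.5-fold for members of lists. For each of 39 gene lists fixed before the data were examined, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. A percentile below 2.5 or above 97.5 was read as outside the central 95% of random lists, as a description of these profiles and not as a test of the construct. Lists with fewer than 5 measured members were given as values.

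Genes were named by a rule fixed in advance: ZHX2, SLC3A2, SLC7A11, GPX4, ACSL4, TFRC and AIFM2 always, then the 10 largest ratios in each direction among genes with a symbol, a mean of at least 1 FPKM and no overlap between the columns of the groups, and up to 4 members per list. The rule had asked for genes past a test. Without one, genes at least 2-fold apart took their place, and list members were taken by the size of their ratio. Gene coordinates are from GENCODE v29 on GRCh38. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

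The steps were tested on simulated profiles of the comparison over 12646 genes: 200 of 200 genes changed 4-fold were recovered at 2-fold or more, 0 of 12446 unchanged genes passed, and 4 of 100 random lists of 25 unchanged genes lay outside the central 95%. The changed genes were drawn from well-expressed genes only, and noise was added to each gene independently. The simulation therefore says nothing about low genes or about lists whose members move together. The noise level was chosen and not taken from these data. Recovery of 4-fold changes thus follows largely from the settings and gives no error rate for these profiles. Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, quantile normalization, and leaving out each column. Alternatives chosen after seeing the data were the first column of each group alone, centring on the median of all genes, the 3 mismatched rows kept as listed or set to their deposited log2 value, and removal of shared members between lists.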

Results

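The series set DB lymphoma cells labelled DB_ZHX2 against DB cells labelled DB_ZHX2_Mut4 (called ZHX2 and Mut4 cells here). ZHX2 is a transcription factor with zinc fingers and homeoboxes, and what the Mut4 form changes is not stated in the labels. The stated purpose was to find pathways that differ between the cells. The series holds no other group, so higher and lower below are relative to the other cells only. The title names SLC3A2 and ferroptosis, an iron-dependent cell death driven by lipid peroxidation. Although 3 libraries per group were labelled, the columns of each group held 1 expression profile multiplied by constants. In Mut4 cells, replicates 2 and 3 were 1.05 and 1.21 times replicate 1 at 23808 of 23808 genes above 0, within a tolerance of 1e-06. In ZHX2 cells the factors were 1.33 and 0.897, at 23368 of 23370 genes, the exceptions being ATG5 and ACSL1. Each group was therefore counted as 1 sample (n = 1), and no difference below has a replicate check or a p-value. Column sums of FPKM were 294109, 309588 and 355116 in Mut4 cells and 287571, 383426 and 258080 in ZHX2 cells.

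**Figure D1:**
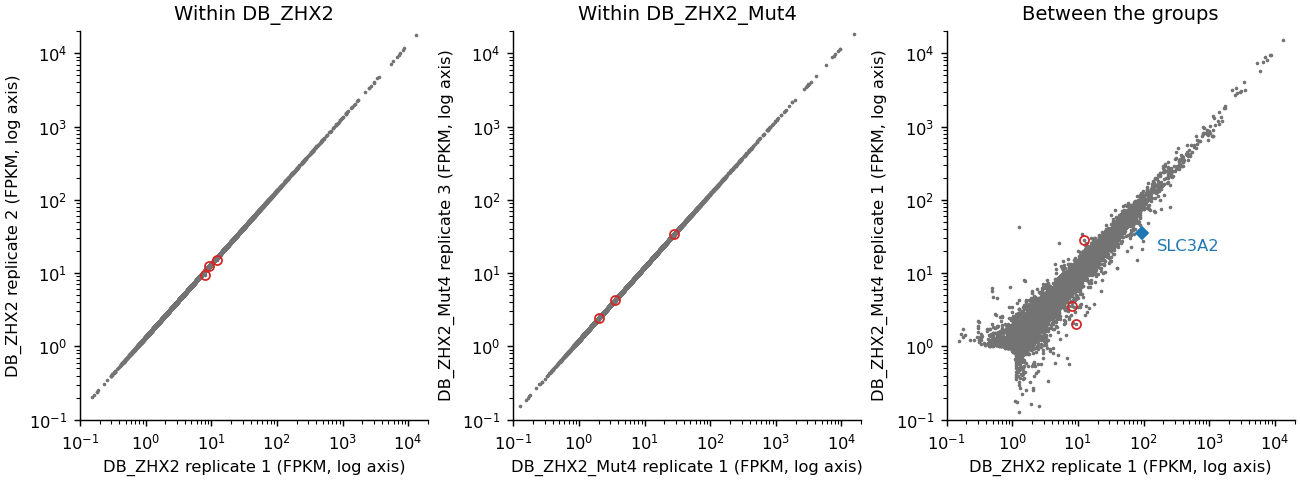
FPKM of each gene passing the filter, on log axes, for 2 columns of ZHX2 cells (left), 2 columns of Mut4 cells (middle) and the first columns of both groups (right); each point is a gene, red circles mark the 3 mismatched rows and the blue diamond SLC3A2. Within a group the points fall on a line, with factors of 1.33 and 1.21, whereas between groups they scatter.

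SLC3A2, the heavy chain that carries several amino acid exchangers to the cell surface, was 2.64-fold higher in ZHX2 cells than in Mut4 cells, at 102.0 against 38.0 mean FPKM (log2 ratio −1.40, Mut4 over ZHX2). The gene lies on chromosome 11, from 62856102 to 62888875 on GRCh38. Of 12643 genes, 31 had a lower ratio than SLC3A2. ZHX2 itself, on chromosome 8 from 122781394 to 122974512, was at 14.9 FPKM in Mut4 cells and 18.0 FPKM in ZHX2 cells (log2 ratio −0.26). The table does not separate the introduced form from the cells' own gene. The ferroptosis regulators fixed for report differed less than SLC3A2: GPX4, which reduces lipid peroxides, was at 56.0 FPKM in Mut4 and 51.1 in ZHX2 cells. ACSL4, which activates polyunsaturated fatty acids, stood at 11.3 and 11.1 FPKM. TFRC, the transferrin receptor, had 51.1 and 57.8 FPKM, and AIFM2, a ubiquinone reductase, 2.002 and 1.842 FPKM. The log2 ratios of these were 0.13, 0.02, −0.18 and 0.08. That of ACSL4 changed sign when Mut4 replicate 3 (−0.05), ZHX2 replicate 1 (−0.02) or ZHX2 replicate 3 (−0.08) was left out, and that of TFRC when ZHX2 replicate 2 was left out (0.0032).

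SLC7A11, the cystine-transporting partner of SLC3A2, had no usable ratio. Its row listed exactly 2 FPKM in Mut4 replicate 1 and 9.29 in ZHX2 replicate 1, a 4.64-fold difference, while the authors' deposited table gave a ratio of 2.44 and a log2 value of 0.53, which is 1.44-fold. The rows of ATG5 and ACSL1 were mismatched too, and their ZHX2 columns, unlike those of SLC7A11, were also off the group's constant ratios. Listed FPKM of replicate 1 in ZHX2 and Mut4 cells were 8.003 and 3.557 for ATG5, and 12.3 and 28.0 for ACSL1. In the authors' deposited table the log2 values of ATG5 and ACSL1 were 0.17 and −0.09, and the ratios 2.13 and 1.94, the latter opposite in direction to the listed FPKM. For all 3 genes the ratio in the authors' deposited table exceeded the fold from its own log2 value by 1. The other 21470 of 21473 rows with both groups above 0 had matching values. No direction is drawn for these 3 genes.

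Across all genes the profiles were close, with a Pearson r of 0.977 across genes, which are not independent replicates. The median log2 ratio was 0.02, and the central 95% of genes lay between −0.59 and 0.59. At least 2-fold apart were 146 genes (1.15%), of which 56 were higher and 90 lower in Mut4 cells. Because the columns differ by constant factors, the split also depended on which columns were averaged: without ZHX2 replicate 2, 89 genes were higher and 65 lower, and the median of all genes moved to 0.17. Leaving out a column rescales a whole profile, so the sign of a ratio or median near 0 follows from which columns are averaged. List percentiles below compare each list with matched genes of the same profiles and so are relative to such a shift. At 1.5-fold, 321 genes (2.54%) were higher and 324 (2.56%) lower in Mut4 cells. The authors' deposited table marked 376 genes as significant, 373 without the mismatched rows, of which 152 were higher in Mut4 and 221 in ZHX2 cells. Marked genes had a q under 0.05 and a deposited log2 value of at least 2-fold, except the 3 mismatched rows. That marking uses neither the filter nor the pseudocount used here, so it is not comparable with the 146 genes. Of the 373, 90 were at least 2-fold apart on the log2(FPKM + 1) scale, with no filter.

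Genes of the endoplasmic reticulum stress programmes were lower in Mut4 cells. All 22 unfolded protein response genes had ratios below 0, with 14 at least 1.5-fold lower and a median log2 ratio of −0.70, below all 10000 random lists. HSPA5, the main chaperone of the endoplasmic reticulum, was 3.09-fold lower in Mut4 cells (86.0 against 267.7 FPKM). The co-chaperones DNAJB9 and DNAJC3 were 2.38- and 2.29-fold lower, and the chaperone HYOU1 2.15-fold lower. Of 30 targets of ATF4 and the integrated stress response, 13 were at least 1.5-fold lower and 29 below 0, with a median of −0.45, again below all random lists. PPP1R15A, a phosphatase subunit that reverses eIF2α phosphorylation, was 4.94-fold lower (16.6 against 85.8 FPKM), and the transcription factor ATF3 3.56-fold lower (6.19 against 24.6 FPKM). DDIT3 and CHAC1, which encode CHOP and a glutathione-degrading enzyme, were each 2.72-fold lower. Replication-dependent histones, the check on poly(A) selection, were lower as well (median −0.37). ATF4 mRNA was at 322.0 FPKM in Mut4 and 378.2 FPKM in ZHX2 cells.

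Amino acid transporters and heat shock genes lay on the same side. Among 18 transporters, 4 were at least 1.5-fold lower in Mut4 cells (SLC3A2, SLC6A9, SLC38A2 and SLC7A3) and 16 had ratios below 0, for a median of −0.42, below all random lists. SLC6A9, a glycine transporter, was 2.47-fold lower, and SLC38A2, a carrier of neutral amino acids, 1.61-fold lower. Of 14 heat shock genes, 5 were at least 1.5-fold lower, with a median of −0.37, below all random lists. HSPA6 was 5.42-fold lower (0.632 against 7.84 FPKM), with a log2 ratio of −2.44 that was −3.44 at a pseudocount of 0.1. The folds were 2.52 for DNAJB1, 4.20 for HSPA1A and 3.55 for HSPA1B. The last pair are near-identical copies whose reads cannot be divided with certainty. Immediate early genes had a median of −0.25 (percentile 0.01 of random lists), with 1 of 14, ATF3, at least 1.5-fold lower.

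With the main filter and without the mismatched rows, the ferroptosis lists as wholes lay inside the random range. Of 21 measured suppressors, 3 were at least 1.5-fold lower in Mut4 cells and 0 higher, with a median of −0.04 (percentile 19.3). These were SLC3A2, the stress-induced SESN2 (1.99-fold) and the ferritin light chain FTL (1.54-fold). With genes filtered at 5 FPKM the percentile of this list was 0.72. With the mismatched rows kept as listed, which adds SLC7A11 to the suppressors, it was 3.02. With these rows set to their deposited log2 values it was 2.83. Among 23 promoters, 2 were at least 1.5-fold lower, CHAC1 and the haem-degrading HMOX1 (1.76-fold), and the median was 0.0011 (percentile 39.1). Glutathione metabolism had a median of 0.10 (percentile 88.6), although IDH1, a source of NADPH, was 3.12-fold lower in Mut4 cells and CTH, of cysteine synthesis, 1.78-fold lower. Iron handling had a median of −0.11 (percentile 3.05), with 3 of 20 members lower, led by the metal transporter SLC39A14 (1.85-fold). Its percentile was 1.74 without a filter, 1.97 with the filter at 5 FPKM, 1.79 after quantile normalization and 1.75 without ZHX2 replicate 2. For NRF2 targets the median was −0.10 (percentile 3.66), with HMOX1 and FTL the 2 of 20 lower. Without ZHX2 replicate 2, when all genes moved upward together, the medians of suppressors, iron handling and NRF2 targets were above 0 (0.12, 0.04 and 0.06), and their percentiles were 20.2, 1.75 and 3.10. Over all alternatives the percentile ranged from 0.72 to 61.8 for suppressors and from 6.66 to 45.8 for promoters.

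**Figure D2:**
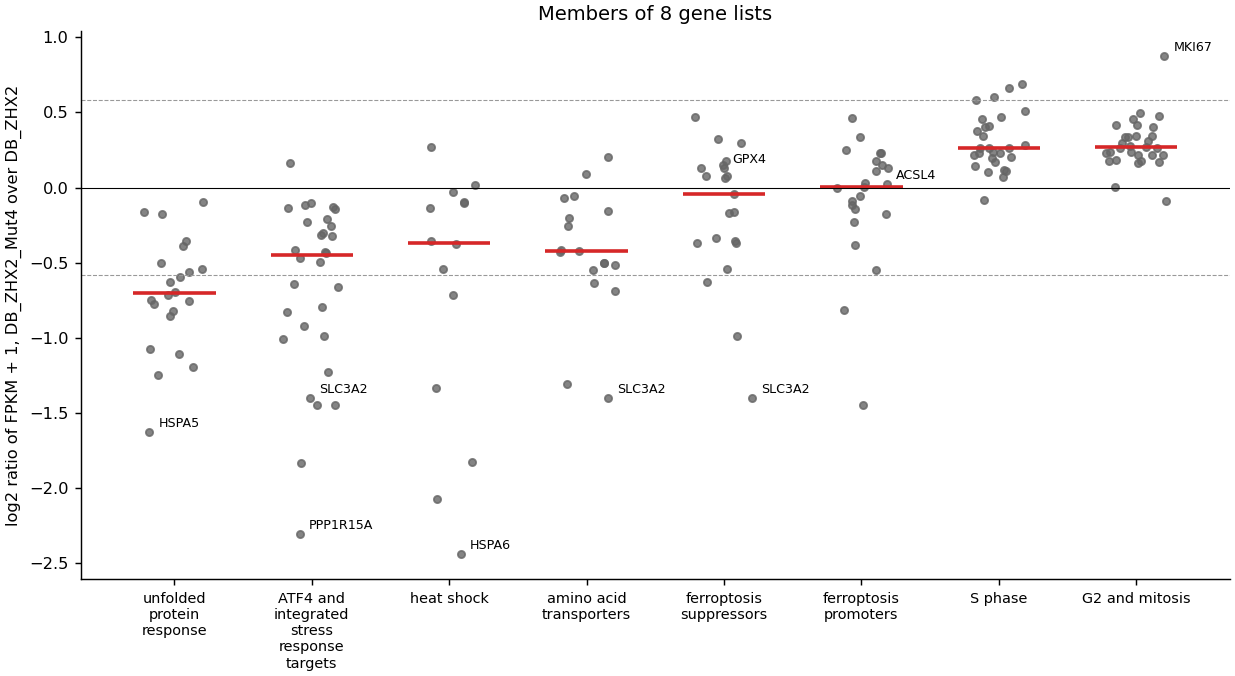
Log2 ratio of FPKM + 1, Mut4 over ZHX2 cells, for each measured member of 8 gene lists; points are genes, spread sideways at random, red bars are list medians and dashed lines mark 1.5-fold. Unfolded protein response members all lie below 0 (median −0.70), and S phase and mitosis members mostly above it (medians 0.26 and 0.27).

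Cell cycle genes were slightly but broadly higher in Mut4 cells. Of 28 S phase genes, 27 had ratios above 0 and 3 were at least 1.5-fold higher, with a median of 0.26, above all random lists. The replication factors CDC45 and MCM5 were 1.61- and 1.58-fold higher, and RRM2, a subunit of ribonucleotide reductase, 1.52-fold. Of 30 genes of G2 and mitosis, 29 were above 0, with a median of 0.27, above all random lists. The proliferation marker MKI67 was 1.83-fold higher (32.3 against 17.2 FPKM). Nuclear-encoded genes of oxidative phosphorylation had a median of 0.19 (percentile 99.99), 37 of 38 above 0 and 0 at 1.5-fold. Mitochondrially encoded genes had a median of 0.20, just inside the random range (percentile 97.4), and above it in 6 of the 14 alternatives, up to 98.2 with the filter at 5 FPKM. After quantile normalization their median was 0 and the percentile 42.6. That setting gives genes of equal rank in both profiles equal values. A median of 0 there reflects equal ranks and cannot decide whether the levels differed.

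Lipid and B lineage genes also had higher medians in Mut4 cells. The other B-cell lists, of germinal centre (0.05) and of plasma and activated B cells (−0.08), lay inside their random ranges. Cholesterol synthesis genes had a median of 0.18 (percentile 99.7), with 19 of 24 above 0 and none at 1.5-fold. INSIG1 and EBP led them at log2 ratios of 0.54 and 0.47. For fatty acid and phospholipid remodelling the median was 0.18 (percentile 98.9, or 97.3 with the filter at 5 FPKM). SREBF1, a regulator of lipid synthesis, was 1.87-fold higher and the desaturase FADS2 1.67-fold higher. Of 26 B lineage genes, 5 were at least 1.5-fold higher and 1 lower, with a median of 0.18 (percentile 99.5). The Fc receptor-like genes FCRL5 and FCRL2 were 2.24- and 2.05-fold higher and the transcription factor SPIB 1.91-fold higher, while FCRLA was 2.04-fold lower.

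Small shifts to the lower side appeared in genes of ribosomes. Among 50 ribosomal protein genes, 46 had ratios below 0 and 0 were 1.5-fold apart; the median was −0.16, below all random lists. It was 0.02 when ZHX2 replicate 2 was left out and all genes moved upward together, with a percentile of 0 there too. RPL23 and RPL30 had the lowest ratios (−0.47 and −0.41). MYC and ribosome biogenesis genes had a median of −0.12 (percentile 0.80), or 0.06 without ZHX2 replicate 2 at a percentile of 0.81. In the main comparison PPAN and RRP9 were lowest in that list, at −0.50 and −0.48. PPAN was listed at 13.77 FPKM in Mut4 and 19.95 FPKM in ZHX2 cells. Its readthrough record PPAN-P2RY11 was listed at 10.1 FPKM in Mut4 cells and at 0 in ZHX2 cells. Because the readthrough shares reads with PPAN, the ratio of PPAN is uncertain. For p53 targets the median was −0.11 (percentile 2.41), but the percentile was 9.74 with no filter and 41.8 with the filter at 5 FPKM, and the median was above 0 with that filter (0.0060) and without ZHX2 replicate 2 (0.05, percentile 1.93). After removal of a trend with GC content and transcript length the p53 percentile was 8.79. Replication-dependent histones, whose transcripts mostly lack poly(A) tails and which were included as a check on selection, had a median of −0.37 over 8 members (percentile 0.01), 2 lower and 1 higher.

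**Figure D3:**
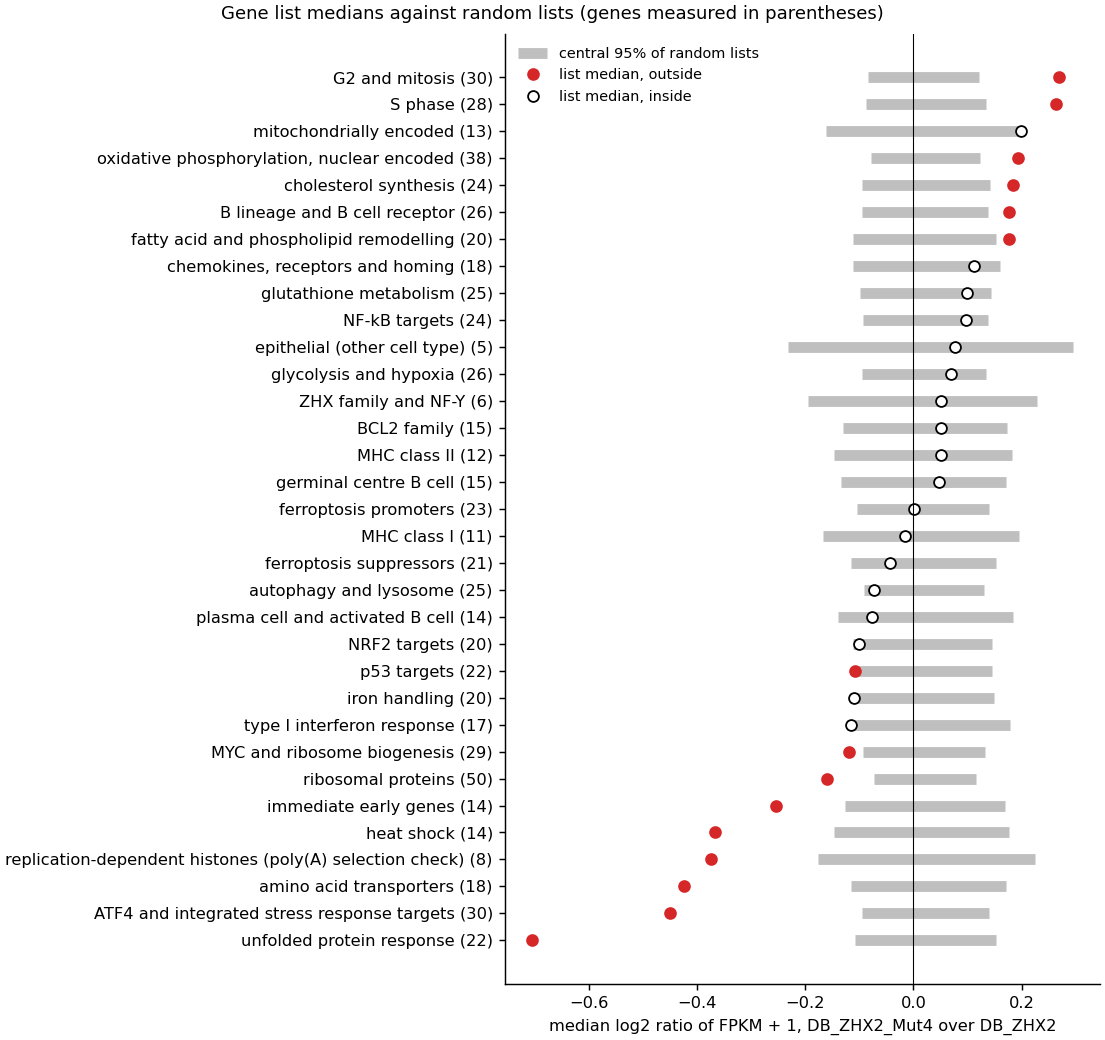
Median log2 ratio of FPKM + 1, Mut4 over ZHX2 cells, of the 33 gene lists with at least 5 measured members; grey bars span the central 95% of 10000 random lists of the same size and expression, and filled red points lie outside them. The unfolded protein response is lowest at −0.70, and 9 lists lie below and 6 above their random range, where 1.65 lists in all would be expected for separate lists of unrelated genes. These lists share members and hold genes that can move together, so 1.65 is not a chance level for them.

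The remaining lists lay inside their random ranges. Medians were 0.10 for NF-kB targets (percentile 89.6), −0.11 for the type I interferon response (3.06), −0.01 for MHC class I (37.4) and 0.05 for MHC class II (63.6). The interferon percentile was 0.60 with no filter, 2.44 without Mut4 replicate 3 and 2.42 without ZHX2 replicate 3. Germinal centre genes had a median of 0.05 (percentile 63.8), plasma cell and activated B-cell genes −0.08 (11.6), the BCL2 family 0.05 (63.8) and glycolysis and hypoxia genes 0.07 (79.3). Autophagy and lysosome genes had a median of −0.07 (percentile 6.09, or 1.07 with the filter at 5 FPKM), chemokines and homing receptors 0.11 (89.4), and the ZHX and NF-Y families 0.05 (62.7). The autophagy and lysosome percentile was 1.465 after removal of a trend with GC content and transcript length. Among markers of other cell types, 5 of 7 epithelial markers passed the filter (EPCAM, KRT5, KRT8, KRT18 and KRT19), at 2.12 to 5.00 FPKM in ZHX2 cells, with a median ratio of 0.08 (percentile 68.2). Of T cell markers, 4 of 16 passed (CD4, TRAC, TRBC2 and LCK), with a median ratio of −0.19, and TRBC2 was highest at 18.4 FPKM in Mut4 and 13.8 FPKM in ZHX2 cells. Of NK cell markers 1 of 9 passed (NKG7, log2 ratio 0.42), and of myeloid markers 2 of 16 (LYZ and AIF1, median −0.35). Of 7 erythroid and 9 fibroblast markers 0 passed. ZHX2 targets described in liver had 2 measured members, CCNE1 and CCNA2, with log2 ratios of 0.58 and 0.16.

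Among the largest ratios, 5 of the 10 genes lower in Mut4 cells were the stress genes PPP1R15A, ATF3, HSPA6, HSPA1A and HSPA1B. BHLHA15, a transcription factor of secretory cells, was 3.58-fold lower (3.67 against 15.7 FPKM). BOLA2 and IGKV3-15 were listed at 0 in Mut4 cells and at 22.9 and 7.60 FPKM in ZHX2 cells. SDHAP2, a pseudogene, and MATR3 were 3.21- and 3.15-fold lower. BOLA2 and MATR3 share sequence with neighbouring or overlapping gene records, so their counting is uncertain. SDHAP2, as a pseudogene, is open to the same doubt. How reads of IGKV3-15 were assigned was not checked, so its listed 0 is not read as a loss. On the other side, INO80B-WBP1 and PPAN-P2RY11, both readthrough records, were listed at 0 in ZHX2 cells and at 12.2 and 10.1 FPKM in Mut4 cells. IKBKGP1, BNIP3P41 and CBWD4P, annotated as pseudogenes, were 4.76-, 4.43- and 3.48-fold higher in Mut4 cells. IKBKGP1 was at 6.25 and 0.524 FPKM in Mut4 and ZHX2 cells, and its log2 ratio of 2.25 was 3.35 at a pseudocount of 0.1. The readthrough NDUFC2-KCTD14 was 2.83-fold higher and the small nucleolar RNA SNORA73B 2.60-fold. Because such records share reads with parent or host genes, their ratios are uncertain. The other 3 were C2orf74 (3.78-fold higher), the splicing regulator MBNL3 (3.67-fold, 4.94 against 0.621 FPKM) and the chemokine CXCL5 (2.49-fold, 2.32 against 0.333 FPKM). At a pseudocount of 0.1 the log2 ratio of MBNL3 was 2.81 instead of 1.87, and that of CXCL5 2.48 instead of 1.32.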

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

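No paired analysis was possible because the columns of a group are 1 profile and the results come from no test. For the same reason the planned trend-free limma fit, camera with an estimated correlation and fry were not run, nor were splits of the samples, and the alternatives for counts were not run because the table holds none. SLC3A2 stayed between −1.52 and −1.22 and ZHX2 between −0.37 and −0.08 over 14 alternatives, and 9 to 11 lists lay below and 6 to 7 above their random range. With a pseudocount of 0.1, which compresses low genes less, 388 genes were at least 2-fold apart, 201 higher and 187 lower in Mut4 cells. With the filter at 5 FPKM, which left 6912 genes, 74 were, 22 higher and 52 lower. Leaving out 1 column at a time only rescales a profile: genes higher ranged from 48 to 89, genes lower from 65 to 120, and genes apart from 144 to 168. Of 806 other values of genes and lists, 797 moved by less than 1.5-fold, 9 by more and 0 reversed, counting as reversals only values at least 1.5-fold from 0. Of the 9, 8 came from the pseudocount of 0.1 (HSPA6, IKBKGP1, MBNL3, CXCL5 and the 4 genes listed at 0 in a group), and the other was SLC7A11, at −0.46 when set to its deposited log2 value. The 797 were largely fixed by the settings and are no sign of robustness. Leaving out a column moved the median of all genes only to between −0.07 and 0.17. Centring or taking the first columns shifts all genes almost alike, and keeping the mismatched rows changes 3 genes. Among list medians, only that of the unfolded protein response lay at least 1.5-fold from 0. What depth limits could not be measured, since the table holds no counts.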

Other observations

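The pathway annotation carried in the table was examined after the data were seen. Among 309 KEGG pathways with at least 10 genes, 23 lay below and 31 above the central 95% of matched random lists, where 15.45 would be expected in all for separate sets of unrelated genes. Pathways share genes that can move together, so 15.45 is not a chance level for them. Low in Mut4 cells were protein processing in the endoplasmic reticulum (151 genes, median log2 ratio −0.15, 21 at least 1.5-fold lower) and the ribosome (133 genes, −0.12). High were DNA replication (35 genes, 0.25), pyrimidine metabolism (41 genes, 0.19), oxidative phosphorylation (120 genes, 0.18) and carbon metabolism (86 genes, 0.16). Ferroptosis, over 29 genes without the mismatched rows, had a median of −0.14 (percentile 0.21), and 6 genes were at least 1.5-fold lower: SLC3A2, SLC39A14, PRNP, HMOX1, MAP1LC3B and FTL. This differs from the lists of ferroptosis suppressors and promoters, which have other members.

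With the mismatched row of SLC7A11 left out, SLC3A2 had the lowest ratio of the amino acid transporters and of the ferroptosis suppressors, while 4 members of the ATF4 list had lower ones. Without the 2 measured members it shares with the amino acid transporters, the ATF4 list kept a median of −0.45 (28 genes, 27 below 0). Without the same 2 members the transporters had −0.42 (16 genes, 14 below 0). Each median was below all 10000 random lists. Only members of the fixed ATF4 list were removed, so the remaining transporters may include other ATF4 targets and are not shown to move apart from them. The lists of the unfolded protein response and of ATF4 targets shared 0 measured members. Chosen after their values were seen, IDH1 and TXNIP, a thioredoxin-binding protein, were both 3.12-fold lower in Mut4 cells.

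All 3 mismatched rows are annotated to KEGG Ferroptosis. Of 38 genes with that annotation 32 passed the filter, and the authors' deposited table marked 5 as significant, or 2 without these rows. As shares of genes passing the filter, 15.6% of Ferroptosis genes were marked, 6.90% without the mismatched rows, against 1.79% of 4461 KEGG-annotated genes. The 1.79% still counted the mismatched rows. The 2 marked genes outside these rows were SLC3A2 and MAP1LC3B2, the latter near the filter at 0.869 FPKM in Mut4 and 1.75 in ZHX2 cells. A share resting on 2 genes was not read as an excess. In the 3 ZHX2 columns the listed FPKM of ATG5 differed from the values its deposited log2 value implies by 4, 4 and 4, that of ACSL1 by −14, −20 and −10, and that of SLC7A11 by 6.41, 8.54 and 5.75. The ZHX2 columns of SLC7A11 kept the group's constant ratios. Taking them as listed, its deposited log2 value implies 6.44 FPKM in Mut4 replicate 1, where 2 was listed. In the authors' deposited table SLC7A11 was marked significant at a q of 0.0575. No explanation was tested for these rows.

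Of the tests below, that of GC content and transcript length was set before its result was seen, and the others after. The first pattern was that the columns of a group are constant multiples of one another. At least 99.991% of genes lay within 1e-06 of a single ratio in each column, where 3 separately sequenced libraries would scatter by counting noise, so the table argues against separate libraries as the source of these columns. How the columns came about is not given in the sources used here, and no other explanation, technical or biological, was tested.

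The second pattern was that the deposited p-values follow the fold change. Over 459 genes above 20 FPKM and 0.3 log2 units, the normal score of the p-value per log2 unit had a median of 4.77, and its 95th percentile was 1.10 times its 5th. A spread estimated gene by gene would vary more than that, so the table argues against it for these genes. The median score corresponds to a standard error of 0.209 log2 units for the deposited log2 ratio. That value is implied by the p-values and is no measure of the spread between libraries.

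The third pattern was the lower level of stress genes in Mut4 cells. Scaling between the profiles was argued against by the median of all genes, 0.02, against −0.70 for the unfolded protein response list. Centring only subtracts the median of all genes, which gave −0.73 for the list, and is no separate test. A trend with GC content or transcript length was argued against too, since after its removal over 12484 genes the list median was −0.70, still below all random lists. What stays open is a difference between the cultures or RNA preparations unrelated to the construct, which cannot be told apart from an effect of either form with 1 profile per group. The replication-dependent histones, fixed as a check on poly(A) selection, were lower with the stress genes (median −0.37, or −0.44 after that removal, over 8 genes). An effect of the Mut4 form or of the ZHX2 form itself also stays open and untested. Without another group, a lower level in Mut4 cells cannot be told apart from a raised level in ZHX2 cells.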
